A study of Mus musculus with 5 samples.

How the data were processed

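The series holds 5 samples from EpiSC9 cells, which were grown with FGF2 at 10 ng/ml on irradiated embryonic fibroblast feeders, per the labels' protocols. Each immunoprecipitation started from 5000000 crosslinked cells, with antibodies against H3K4me1, H3K4me3, H3K27ac or H3K27me3. The remaining sample, an input library, was not used here. Groups follow the antibody given in the labels, with 1 library per mark, so peaks were called per library as far as the lists show, and no replicate comparison could be made.

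The values analysed are 4 lists of peak intervals on mm9 with a score per peak that the authors deposited. Bowtie 0.12.9, MACS 1.4 and Cufflinks, without a version, are named in the submitters' processing notes, which give no role or order. The control used for calling, the treatment of duplicate reads and the calling threshold are not given in the sources used here. MACS of this generation writes a score of 10 times the negative log10 of p, and the lowest score in the lists, 50, would be a p of 1e-05 on that scale. No header or label states this, so the scores served to rank or filter peaks within a list and for rank correlations across overlapping peaks of paired lists. Many scores stop at about 3100, which hides differences among the strongest peaks, above all of H3K4me3. No read counts were used, so the depth of each library is unknown. A deeper library or a better antibody gives more and wider peaks, which affects every share that involves its list, and the longest list, H3K4me1, has the most chance overlap.

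Intervals were counted as overlapping when they shared at least 1 bp. For each of the 6 pairs of lists, the share of peaks of the shorter list that overlapped the other was set against 1000 circular shifts within each chromosome, which keep peak widths and spacing. Shifts wrapped at the last peak end over all 4 lists, since mm9 chromosome lengths were not used here. The p is two-sided, with 0.002 as the smallest value possible, and was adjusted by the Benjamini-Hochberg method over the 6 pairs or over the 6 shares of a class test. In class tests the H3K27ac and H3K27me3 lists were shifted together. Distal H3K4me1 elements were peaks with no H3K4me3 peak within 1 kb, so H3K4me3 stood in for promoters. H3K27ac peaks were joined within 12.5 kb and H3K27me3 peaks within 5 kb, and the resulting regions were ranked by covered length, because scores of peaks do not add up. Densities per Mb use the same chromosome ends. Coordinates are 1-based positions of mm9.

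Shares carry 95% Wilson intervals. These, and the p-values over positions, leave out variation between cultures, immunoprecipitations and sequencing runs. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The overlap test was tested on simulated data with 200 shifts per run. A planted coincidence of 5% of 33600 H3K27ac peaks with H3K4me1 was recovered as 4.99% and called in 10 of 10 runs, and a planted 40% as 40.1%. A planted avoidance of 70% between H3K27me3 and H3K27ac was recovered as 69.1%, and with no relation planted between H3K27me3 and H3K4me3, 1 of 40 runs was called. The runs with no relation moved the real H3K27me3 peaks by the same kind of shift as the test, so few calls followed from the design. The planted runs placed peaks at random, without the shared regional clustering of the real lists. Calls due to regional density were therefore not examined.

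The tests, the class definitions and the rule for named regions were fixed before the data were examined. Without an annotation of mm9, that rule takes the 5 widest H3K4me3 peaks, the 5 H3K27ac clusters and the 5 H3K27me3 domains with the largest covered length, by position and without gene names. An annotation of another build was at hand and its positions were not used, so promoter states of genes, tests of gene lists, assignment of elements to genes and the check of feeder and differentiation markers were not run. The share of signal from feeder cells is therefore unknown. Other settings fixed at the same time were a stricter overlap, a stricter score, equal numbers of peaks per list, autosomes only, merged peaks, independent random placement (100 draws), other distances for distal elements and other joining distances. Shifts of 50 kb to 1 Mb, X alone with either kind of shift and autosomes alone for domains were added after the data were examined. So were 2 score filters for densities by chromosome, 2 settings that thin H3K4me3 alone, and the test of H3K4me3 in long domains. Comparisons with the product of the shares of the marks were also not among the tests fixed beforehand.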

Results

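Chromatin immunoprecipitation followed by sequencing mapped 4 modifications of histone H3 in EpiSC9, a line of mouse epiblast stem cells. Such cells derive from the epiblast of the implanted embryo and represent the primed state of pluripotency. H3K4me1 lies at enhancers and beside promoters, and H3K4me3 marks promoters. H3K27ac marks active promoters and enhancers, and H3K27me3 is placed by Polycomb complexes at silenced genes. Each mark had 1 library and 1 peak list and no replicate, so every share and fold below describes these libraries, and the permutation tests run over genome positions, not over cultures. The read totals behind the lists are unknown, and the 95% Wilson intervals cover counting over peaks only.

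H3K4me1 gave the longest list, with 76772 peaks that covered 145.7 Mb of mm9 and had a median width of 1541 bp (interquartile range 1155 to 2208). The H3K27ac list held 33600 peaks over 38.3 Mb, with a median width of 818 bp. H3K4me3 peaks numbered 28941 over 33.5 Mb, with a median width of 981 bp. The H3K27me3 list was the shortest, with 16975 peaks over 12.4 Mb and a median width of 405 bp. Its longest peak nevertheless reached 16250 bp, against 8039 bp for H3K4me3. The score of each peak is the authors' and was used within a list, except for the rank correlations between paired marks given further on. It reached 3100 or more, a level at which many scores stop, in 25.4% of H3K4me3 peaks, 3.06% of H3K27ac peaks, 0.401% of H3K27me3 peaks and 0 H3K4me1 peaks.

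The maps first allow the question of which marks lie together in primed cells. H3K4me3 and H3K27ac coincided strongly: 14236 of 28941 H3K4me3 peaks (49.2%, 95% interval 48.6 to 49.8) overlapped H3K27ac, 17.9-fold above the mean of 1000 circular shifts (2.75% ± 0.152, SD over shifts). H3K4me1 was shared by both, since it overlapped 83.2% of H3K4me3 peaks (82.7 to 83.6, 9.19-fold) and 77.8% of H3K27ac peaks (77.4 to 78.2, 8.69-fold). In the other direction, 31.4% of H3K4me1 peaks touched H3K4me3 and 30.9% touched H3K27ac. H3K27me3 lay on H3K4me3 in 5640 of 16975 peaks (33.2%, 32.5 to 33.9), 19.2-fold above the shifts, and on H3K4me1 in 7019 peaks (41.4%, 6.94-fold). The shares depend on list length. With equal numbers of top-scoring peaks per list, H3K4me1 overlapped 36.95% of H3K4me3, 41.23% of H3K27ac and 20.87% of H3K27me3 peaks. These were still 10.4-fold, 11.7-fold and 9.7-fold above the shifts. H3K27me3 then lay on H3K4me3 in 27.79% of its peaks.

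H3K27me3 and H3K27ac were the exception among the 6 pairs, with less overlap than the shifts gave. Only 215 H3K27me3 peaks (1.27%, 1.11 to 1.45) touched H3K27ac, against 1.92% ± 0.165 (SD) after shifting, a fold of 0.658. Each of the 6 two-sided permutation tests gave an adjusted p of 0.002, the smallest that 1000 shifts can give. Against shifts of 50 kb to 1 Mb, which keep the regional density of peaks and were added after the data were examined, the 5 enrichments fell to between 4.08-fold and 10.8-fold and the depletion deepened to 0.416, while peaks scoring at or above their list's median gave 0.389 for the depletion. On the X chromosome alone, likewise added later, the H3K27me3 and H3K27ac pair was 2.12-fold above whole-chromosome shifts (78 of 5535 H3K27me3 peaks, permutation adjusted p = 0.00599) but 1.15-fold above shifts of 50 kb to 1 Mb (permutation adjusted p = 0.454), and the other pairs ranged from 3.4-fold to 52.5-fold under the former and from 1.8-fold to 25.1-fold under the latter.

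**Figure D1:**
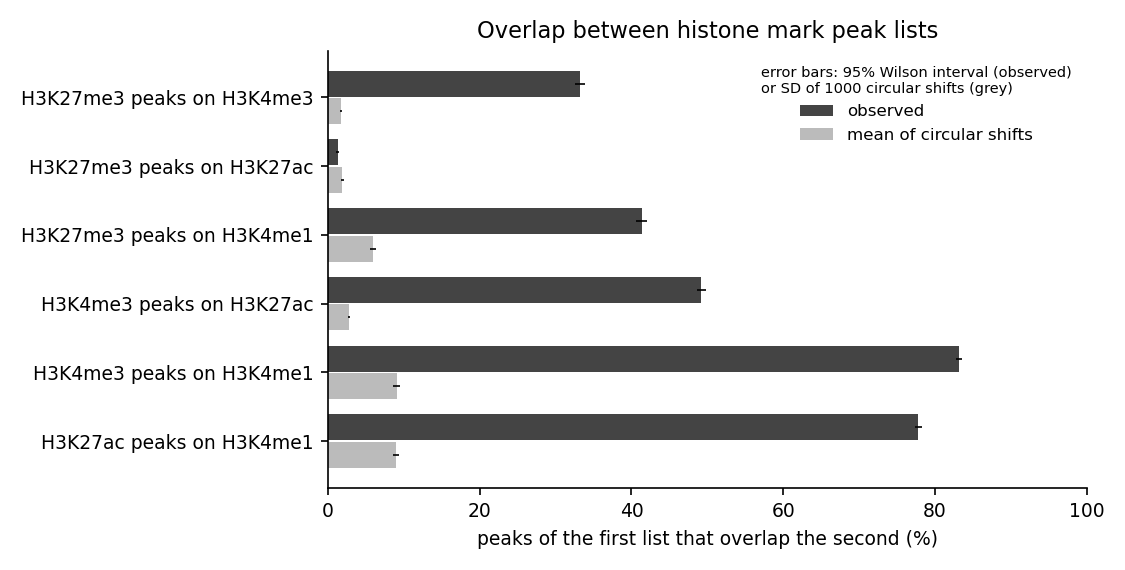
Horizontal bars give the percent of peaks of the first-named list that overlap the second, observed (dark, with 95% Wilson interval) and as the mean of 1000 circular shifts (grey, with SD). The observed bar exceeds the grey bar in 5 of 6 pairs, and for H3K27me3 on H3K27ac it is shorter, 1.27% against 1.92%.

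Elements that carry H3K4me1 away from promoters were then sorted by their H3K27 state, which separates active from Polycomb-marked and unmarked enhancers. Of the H3K4me1 peaks, 51179 (66.7%, 66.3 to 67) had no H3K4me3 peak within 1 kb. H3K27ac without H3K27me3 was found on 9520 of these distal elements (18.6%, 18.3 to 18.9), 5.59-fold above the shifted mean of 3.33% (adjusted permutation p = 0.004). Neither mark was found on 41200 (80.5%, 80.2 to 80.8), fewer than the 95.7% after shifting (adjusted permutation p = 0.004). H3K27me3 alone was rare, with 433 elements (0.846%, 0.77 to 0.929), and did not differ from the shifted 0.91% (adjusted permutation p = 0.384). Both marks met on 26 elements (0.0508%, against 0.0317% after shifting, adjusted permutation p = 0.0689, and 0.167% from the product of the shares of the marks).

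The classes differed in peak size, though wider peaks meet more peaks of any kind, and in their distance from the nearest H3K4me3 peak. Distal elements with H3K27ac alone had a median H3K4me1 width of 2086.5 bp and a median score of 210.8, against 1378 bp and 99.03 for elements with neither mark. Elements with H3K27me3 alone stood between these, at 1605 bp and 124.2. They lay close to H3K4me3, at a median of 4.48 kb (interquartile range 1.96 to 17.7), whereas the medians were 24.9 kb for H3K27ac alone and 25.4 kb for neither mark. The H3K27me3 share depended on how distal was defined: it was 1.09% when only overlap with H3K4me3 was excluded (1.19-fold, adjusted permutation p = 0.012) and 0.462% when H3K4me3 was excluded within 5 kb (0.511-fold, adjusted permutation p = 0.0024). Under other settings it was called above the shifts. It was 2.63% (3.52-fold) among peaks at or above the median score of every list and 2.68% (2.88-fold) when H3K4me3 alone was limited so. With equal numbers of top-scoring peaks it was 2.58% (2.05-fold), and each of these 3 had an adjusted permutation p of 0.002. On X it was 21.6% (4.32-fold, adjusted permutation p = 0.004), but on autosomes 0.761% (0.852-fold, adjusted permutation p = 0.045). These values are against whole-chromosome shifts, and shifts of 50 kb to 1 Mb were not run for distal elements. For all H3K27me3 peaks on H3K4me1 on X, the latter lowered the fold from 4.6 to 1.83, so regional density may account for much of the X value. The share with H3K27ac alone rose to 30.9% when H3K4me1 peaks below the median score were left out.

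At H3K4me3 peaks, taken as promoter-like regions, H3K27ac was the more frequent of the H3K27 marks. H3K27ac without H3K27me3 marked 13937 of 28941 peaks (48.2%, 47.6 to 48.7), 17.6-fold above the shifts. H3K27me3 without H3K27ac, the bivalent combination, marked 4518 peaks (15.6%, 15.2 to 16), 17.8-fold above the shifts. Both H3K27 marks met on 299 peaks (1.03%, 0.923 to 1.16), fewer than the 8.19% that the product of the shares of the marks gives, and neither lay on 10187 (35.2%, 34.7 to 35.8), against 96.4% after shifting. Against the shifts, all 4 classes had an adjusted permutation p of 0.002; for the class with both marks this compares with positions off H3K4me3 (0.022%) and does not test whether the marks meet. The class with both marks fell to 0.456% among peaks at or above the median score of each list and was 4.22% on X, where H3K27me3 alone marked 8.96%.

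**Figure D2:**
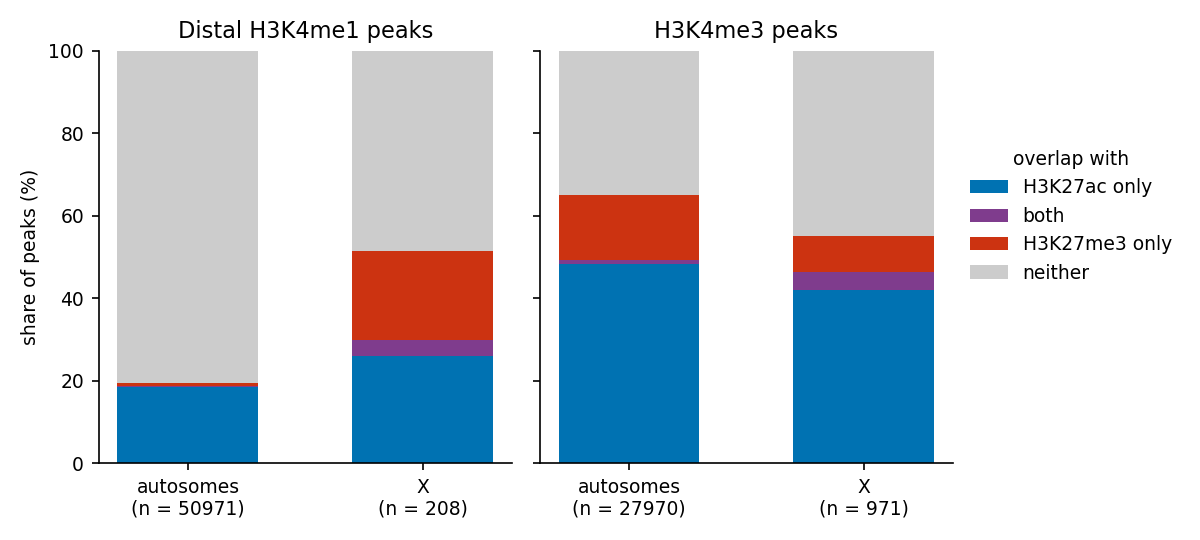
Stacked bars give the percent of distal H3K4me1 peaks (left) and of H3K4me3 peaks (right) that overlap H3K27ac only, both H3K27 marks, H3K27me3 only or neither, on autosomes and on X, with the number of peaks under each bar. On autosomes 18.6% of distal H3K4me1 peaks and 48.4% of H3K4me3 peaks carry H3K27ac only, and the 208 distal elements on X carry H3K27me3 only in 21.6%.

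Peak strength followed these classes. H3K4me3 peaks with H3K27ac alone had a median width of 1298 bp and a median score of 2606.1, and 44.7% of them scored 3100 or more. Bivalent peaks were of similar width, 1211 bp, with a median score of 909.1. Peaks with neither H3K27 mark were narrow and weak, at 497 bp and 180.7, and the 299 with both were the widest class at 2137 bp. Since wider peaks meet more peaks of any kind, width is not independent of class. H3K27me3 peaks on H3K4me3 had a median score of 153.8 and a width of 753.5 bp, against 61.51 and 366 bp for those without H3K4me3. Across overlapping peaks, Spearman's rho between the scores of paired marks over the 6 pairs lay between -0.141 (H3K27me3 with H3K27ac, 215 peaks) and 0.182 (H3K4me3 with H3K27ac, 14236 peaks). Scores that stop near 3100 and the restriction to overlapping peaks limit what these values can show, and no p is given because peaks within a library are not independent replicates.

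The 5 widest H3K4me3 peaks differed in the other marks they held. Those on chromosome 18 at 55144889 to 55152927 (8.04 kb), chromosome 19 at 5797091 to 5804314 (7.22 kb) and chromosome 14 at 106291446 to 106298648 (7.2 kb) each scored 3100 and held 2 H3K27ac peaks, which covered 7.91, 5.58 and 6.56 kb in that order, and 2 H3K4me1 peaks. The other 2, on chromosome 11 at 3061982 to 3069999 (8.02 kb) and at 3090095 to 3097214 (7.12 kb), scored 915.9 and 1823.8 and overlapped no peak of any other mark. Both belonged to the same run of 26 H3K4me3 peaks, described further on, and are not separate examples.

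H3K27ac peaks gathered into clusters of very unequal size. Joining peaks within 12.5 kb gave 16953 clusters, of which 9033 (53.3%) held a single peak. The top 1% by H3K27ac-covered length, 170 clusters, covered 13.7 to 47.7 kb each, with a median of 17.9 kb against 1.52 kb over all clusters, and held 8.7% of the covered length. A distal H3K4me1 element lay in 155 of them (91.2%), against 42.9% of all clusters, and H3K4me3 in 163 (95.9%), against 52.3%. Since longer regions meet more peaks of any kind, these shares carry no test. Without H3K27ac peaks within 1 kb of H3K4me3, the number of clusters was 10674.

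The cluster with the largest covered length was on chromosome 15 at 77620934 to 77697873, where 25 H3K27ac peaks covered 47.7 kb and 15 H3K4me1 peaks covered 57.4 kb. Next came chromosome 2 at 165674540 to 165740619, with 12 H3K27ac peaks over 41.4 kb, and chromosome 9 at 121186077 to 121282942, with 27 peaks over 38.5 kb. A second cluster on chromosome 9, at 72626636 to 72732124, held 26 peaks over 38.3 kb, and the fifth, on chromosome 14 at 27851356 to 27919761, held 16 peaks over 37.3 kb. Each of these 5 clusters also held between 2 and 9 H3K4me3 peaks and 0 H3K27me3 peaks, while 10 of the 170 overlapped H3K27me3.

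H3K27me3 peaks joined within 5 kb formed 7561 domains, 4299 (56.9%) of a single peak. Each of the 215 domains that covered 10 kb or more overlapped H3K4me3, against 16.8% ± 2.64 (SD) of these domains after shifting (permutation p = 0.002), and 16 overlapped H3K27ac. With joining within 1 kb the count was 179 of 179, and within 12.5 kb it was 234 of 236. Of all domains, 36.9% overlapped H3K4me3. That share was 57.2% for the 4655 autosomal domains and 4.41% for the 2900 on X, a split made after the data were examined.

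Domain length fell off steeply from the top. On chromosome 15 at 102732520 to 102901305, 52 H3K27me3 peaks covered 154 kb of a 168.8 kb span, together with 31 H3K4me3 and 25 H3K4me1 peaks and 0 H3K27ac peaks. The domain on chromosome 6 at 52099332 to 52228455 covered 121.1 kb and held 41 H3K4me3 peaks and 8 H3K27ac peaks over 8.99 kb. On chromosome 11 at 96111402 to 96236792, H3K27me3 covered 107.7 kb, with 33 H3K4me3 peaks and 10 H3K27ac peaks over 7.83 kb. The domains on chromosome 2 at 74484673 to 74593091 (99.2 kb covered) and on chromosome 9 at 91243710 to 91318923 (62.7 kb) held 38 and 15 H3K4me3 peaks and 0 H3K27ac peaks.

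**Figure D3:**
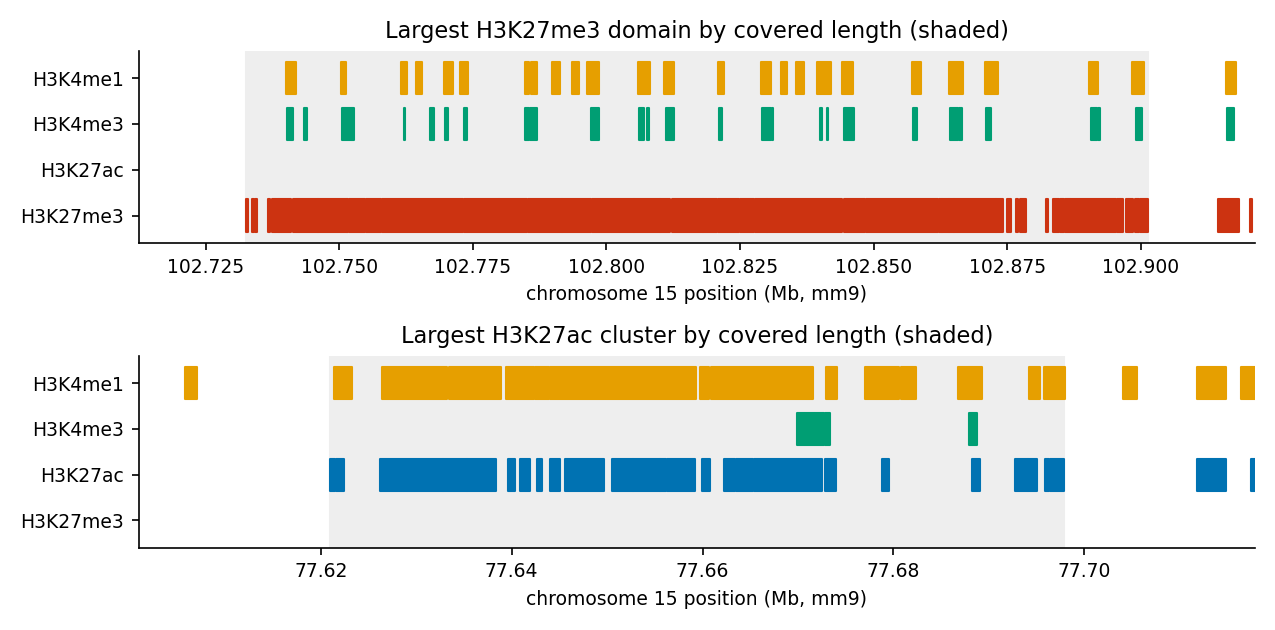
Peaks of the 4 marks along the H3K27me3 domain (top) and the H3K27ac cluster (bottom) with the largest covered length, both on chromosome 15, with mm9 position in Mb on the horizontal axis and the region shaded. The domain shows 31 H3K4me3 peaks inside 154 kb of H3K27me3 and 0 H3K27ac peaks, and the cluster shows 25 H3K27ac peaks and 0 H3K27me3 peaks.

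The X chromosome stood outside the range of the 19 autosomes for the density of all 4 marks. H3K27me3 reached 33.2 peaks per Mb on X, against an autosomal median of 4.59 and range of 2.57 to 8.3, so that 32.6% of all H3K27me3 peaks (31.9 to 33.3) were on X. The other marks were sparser there. H3K4me1 had 2.46 peaks per Mb on X against an autosomal median of 32 (22.1 to 50.2), a ratio of 0.0771, while the ratio was 0.355 for H3K27ac and 0.509 for H3K4me3.

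The shares of peaks that combined also differed on X. H3K4me1 overlapped 19.8% of the 971 H3K4me3 peaks on X, against 79.7% to 90.5% on single autosomes. The density of the H3K4me1 list bears on this share, since shifting gave 0.567% on X and 9.34% on autosomes. Against these shifts the overlap was 34.9-fold on X and 9.14-fold on autosomes. A share cannot pass 100%, so the higher shifted share on autosomes limits the fold there. Neither the shares nor the folds can therefore decide whether the association was weaker on X. H3K27ac overlapped 46.2% of H3K4me3 peaks on X, within the autosomal range of 46 to 53.7%. H3K27ac peaks met H3K27me3 in 8.71% of cases on X, against 0.0533% to 0.727% on autosomes, and shifts of 50 kb to 1 Mb on X gave 7.96% (permutation p = 0.587). Of the 5535 H3K27me3 peaks on X, 5280 (95.4%) touched no other mark, against 4046 of 11419 (35.4%) on autosomes. X peaks of H3K27me3 were weak, with a median score of 60.09 and width of 362 bp, below every autosome (68.79 to 92.45 and 407 to 524 bp). The H3K27me3 density ratio of X to the autosomal median, 7.25, was 3.5 among peaks at or above the median score and 1.05 among peaks scoring 100 or more, and the H3K4me1 ratio was 0.0249 and 0.0351 under the same settings, which were added after the data were examined.

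H3K27me3 was unevenly spread along X. Of 167 bins of 1 Mb, 64 held 0 H3K27me3 peaks, and 49 with 50 or more held 84.2% of the X peaks. The densest bin, from 96 to 97 Mb, held 255.

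**Figure D4:**
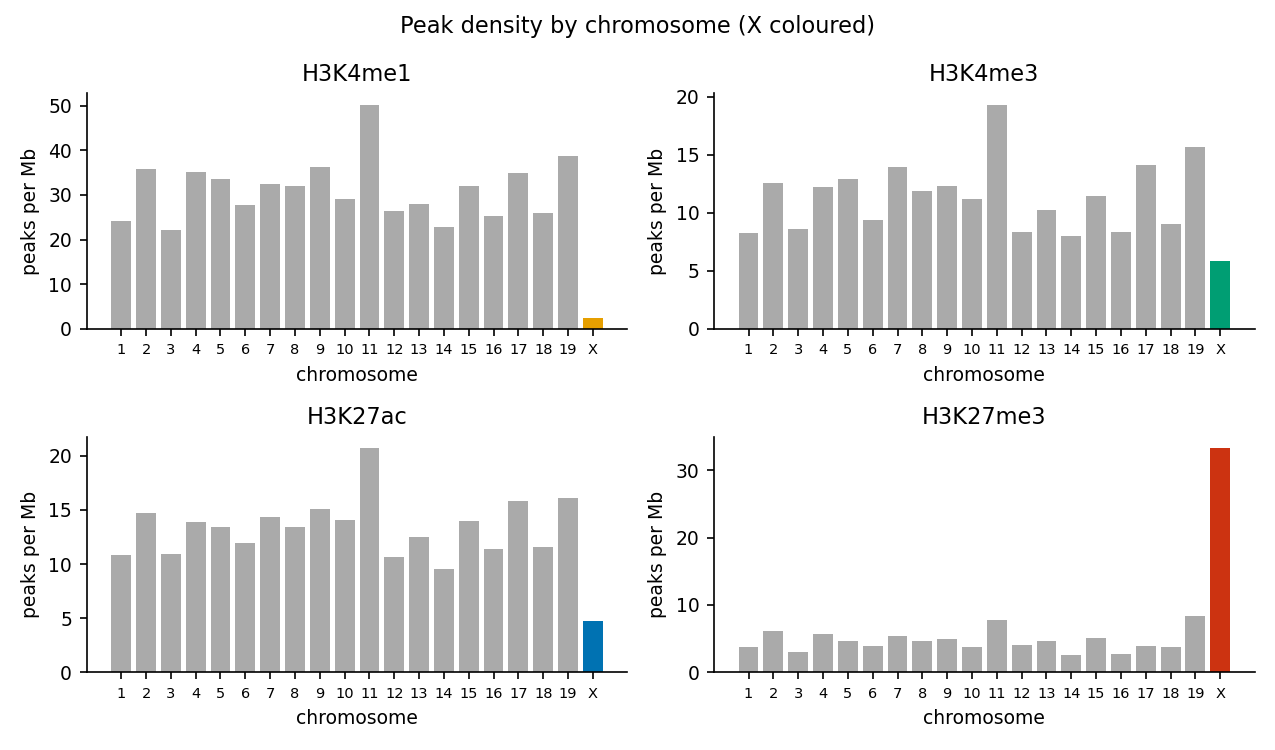
Peaks per Mb on each autosome (grey) and on X (coloured) for the 4 marks, each panel with its own vertical axis from 0. X has the highest H3K27me3 density, 33.2 peaks per Mb, and the lowest density of the other 3 marks, including 2.46 for H3K4me1.

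**Figure D5:**
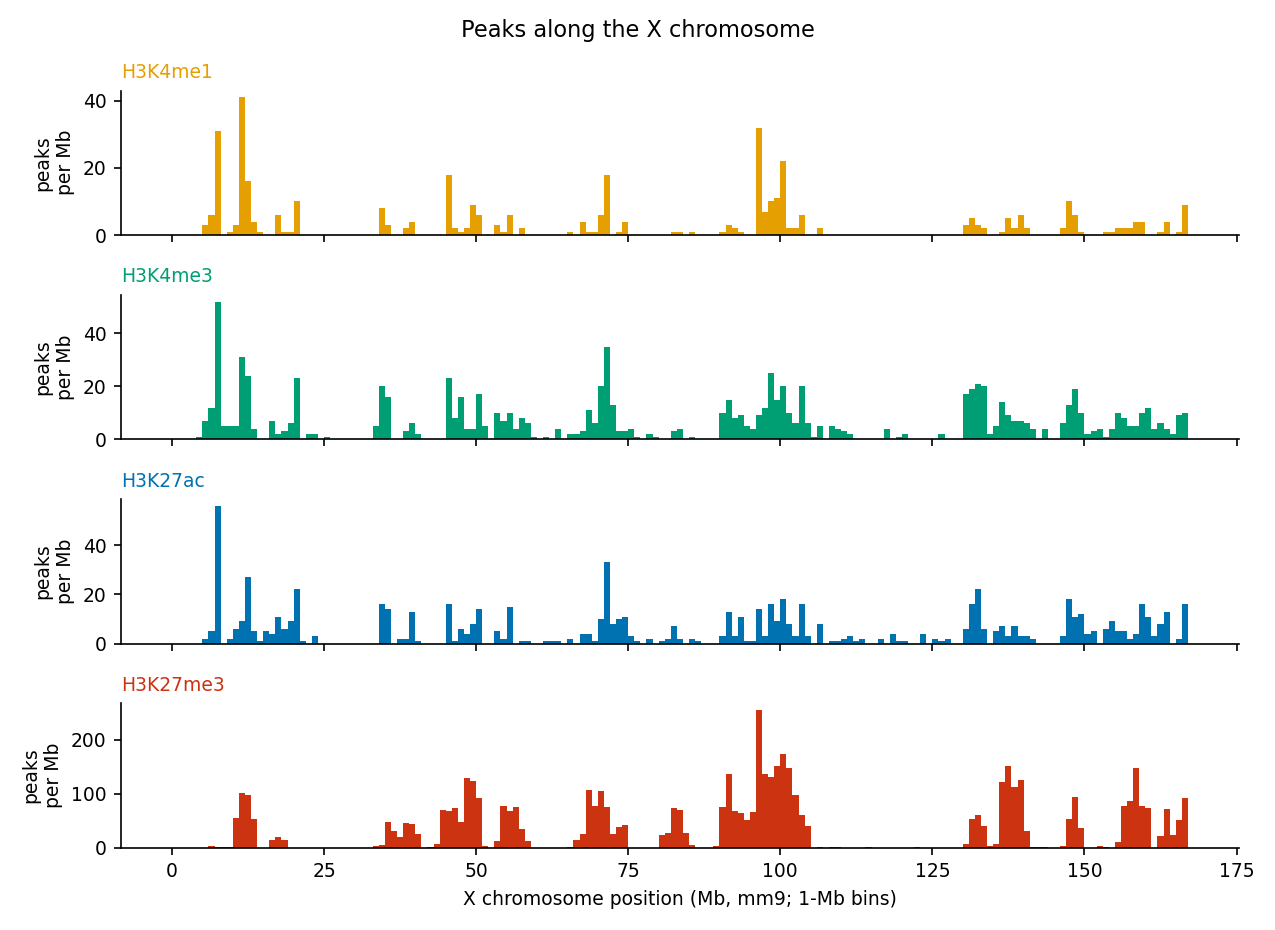
Number of peaks in bins of 1 Mb along the X chromosome (mm9 position in Mb) for the 4 marks, each with its own vertical axis from 0. H3K27me3 forms blocks of up to 255 peaks per bin separated by stretches with 0 peaks.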

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

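X alone, shifts of 50 kb to 1 Mb, autosomal domains, thinning of H3K4me3 alone and score filters for chromosome densities were chosen after the results were seen. All 36 values for pairs of marks under settings fixed beforehand, and all 24 such and 6 added values for H3K4me3 classes, kept direction and call, as did 16 of 18 added for pairs; on X, H3K27me3 on H3K27ac was at 2.12-fold, and at 1.15-fold without a call (adjusted permutation p = 0.454) with shifts of 50 kb to 1 Mb. Distal elements with H3K27ac, and with neither mark, kept theirs throughout. The share of distal elements with H3K27me3 alone (0.846%), and with any H3K27me3, rose above the shifts among peaks at or above the median score (2.63% and 2.68%), with equal numbers of top peaks (2.58% and 2.73%), with overlapping H3K4me3 alone excluded (1.09% and 1.14%) and on X (21.6% and 25.5%). It passed below them on autosomes (0.761% and 0.796%) and with H3K4me3 excluded within 5 kb (0.462% and 0.511%). Thinning H3K4me3 alone, by which H3K4me1 beside a dropped H3K4me3 peak counts as distal, also put them above the shifts, at or above the median score (2.68% and 2.79%) and for the top peaks (1.82% and 1.91%), and thinning H3K4me1 alone gave 0.933% (no call). For the other settings the cause was not tested, and shifts of 50 kb to 1 Mb were not run for distal elements. Distal elements with both marks (26) were called above the shifts at 50% overlap (0.043%), at or above the median score (0.0535%, or 0.0873% for H3K4me1 alone), with equal numbers (0.151%), with overlap alone excluded (0.0551%), with H3K4me3 alone thinned (0.118% and 0.0878%) and on X (3.85%). These calls compare with shifted positions, where H3K27ac is rarer, and do not test whether the marks meet. In the main setting both marks met at 0.304 of the product of their shares (0.0508% against 0.167%).

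H3K27ac clusters away from H3K4me3 numbered 10674, and their top 1% all held a distal element (100%). For clusters of all H3K27ac peaks, that share of the top 1% was 91.2% with joining within 12.5 kb and 76% within 5 kb. Of H3K27me3 domains on all chromosomes, 36.9% held H3K4me3, and 29.6% and 46.1% with joining within 1 and 12.5 kb; on autosomes alone there were 4655 domains and 57.2% held it. The X to autosome ratio among peaks at or above the median score was 0.0249 for H3K4me1, 0.397 for H3K4me3 and 3.5 for H3K27me3; a score of 100 or more gave 0.0351 for H3K4me1 and 1.05 for H3K27me3. Settings that need gene starts were not run. Unknown depth limits what absence from a list shows.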

Other observations

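Tests of the X patterns were chosen after the results were seen, except the tests of weaker H3K4me1 enrichment on X and of H3K27me3 in place of H3K4me1, whose bounds were set before their values were known. Merging the 4 lists gave 89812 separate regions. H3K4me1 alone was the most frequent state, with 42160 regions (46.9%). H3K4me1, H3K4me3 and H3K27ac shared 10276 regions (11.4%), and H3K4me1 and H3K27ac shared 9501 (10.6%). H3K4me1 accompanied the bivalent pair in 2938 regions (3.27%), while H3K4me3 with H3K27me3 and no other mark made up 247. Regions that held all 4 marks numbered 400, the widest state with a median of 5054 bp. Merging joins touching peaks, so regions with more marks are wider in part by construction. Marks in the same region can be linked through peaks of another mark and need not overlap. Only 202 H3K27ac peaks overlapped H3K27me3, so in many of the 400 regions these marks did not touch.

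H3K27ac was also found away from both H3K4 marks. Of its 33600 peaks, 13846 (41.2%) lay on H3K4me1 without H3K4me3, 12295 (36.6%) on both and 5605 (16.7%, 16.3 to 17.1) on neither, and the last were weak, with a median score of 81.86 against 447.4 for those on both. H3K4me1 peak intervals often spanned the centre of an H3K4me3 peak. The midpoint of 20034 H3K4me3 peaks (69.2%) lay inside an H3K4me1 peak, and 13111 (45.3%) lay wholly inside one. Only 4037 (13.9%) touched H3K4me1 with their midpoint outside it. These counts come from peak limits, which are wider than the underlying signal maxima. They cannot show whether H3K4me1 signal lay at the centre or only on the flanks.

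H3K27me3 peaks were dense and weak on X, mostly away from the other marks. Gene-rich DNA as the whole cause is argued against, because bins of 1 Mb with 5 or more H3K4me3 peaks held a mean of 63.6 H3K27me3 peaks on X and at most 11.5 on an autosome, a ratio of 5.52. A uniform excess of X copies over the control is argued against as the whole cause, since alone it would reach all X bins alike. Of the 13 X bins with 20 or more H3K4me3 peaks, 2 held 1 and 0 H3K27me3 peaks, while the other 11 held 6 to 173. Scores of H3K27me3 peaks on X (median 60.09) were near the lowest in the list (50), so local coverage could also shape these counts. An excess combined with uneven local coverage was not tested. The other 3 marks were below every autosome on X (0.73 of the lowest autosome for H3K4me3, the highest of them). Their low density cannot decide, since the density on X without such an excess and the control of each list are unknown. An inactive X coated with H3K27me3 may also contribute and was not settled. The overlap of H3K27ac with H3K27me3 on X was 1.98 times the whole-chromosome shifts (69 of 792 peaks, permutation p = 0.00599). Against shifts of 50 kb to 1 Mb it was 1.1 times (permutation p = 0.587), so the excess went largely with regional density. The avoidance seen on autosomes (0.529 times the whole-chromosome shifts) was nevertheless not seen on X against either kind of shift. Over all chromosomes, shifts of 50 kb to 1 Mb gave 0.416 for H3K27me3 peaks on H3K27ac. At H3K4me3 peaks, both H3K27 marks met at 0.693 of the product of their shares on X, against 0.112 on autosomes. The H3K27me3 list also held 21 peaks on Y (median score 60.95, top score 568.1); whether they come from a Y or from similar sequence elsewhere, the sex of the line, any feeder share and the control stay untested.

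H3K4me1 peaks were nearly missing on X, at 0.0771 of the autosomal density. Fewer regulatory regions on X are argued against as the whole cause, since H3K27ac and H3K4me3 kept ratios of 0.355 and 0.509. H3K27me3 in place of H3K4me1 is argued against as the whole cause, as far as called peaks show. In X bins with 2 or fewer H3K27me3 peaks, H3K4me1 overlapped 29 of 171 H3K4me3 peaks (17%, 1.35 to 24.4 when blocks of 10 Mb were resampled). That share was far below the autosomes (79.7% or more) and beside 21% in bins with 20 or more. Of the 171 peaks, 52 lay at 7 to 8 Mb and 23 at 20 to 21 Mb. H3K27me3 peaks on X scored near the lowest score in the list, so few peaks do not show that the mark was absent. A uniformly weaker H3K4me1 enrichment on X may contribute and was not settled. Limiting autosomal H3K4me1 by score to the X density (6088 peaks) left 17.1% (16.6 to 17.5) of autosomal H3K4me3 peaks overlapped, against 19.8% (17.4 to 22.4) on X. For H3K27ac peaks the shares were 18.6% and 24.2%. The limit was set per Mb, and X also held fewer H3K4me3 and H3K27ac peaks per Mb. A limit per H3K4me3 peak would keep more autosomal H3K4me1 peaks, so the closeness of these shares cannot decide. What would weaken H3K4me1 on X, such as a control with another X content or lower depth per copy, was not tested.

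Both of the widest H3K4me3 peaks without another mark lay in a run at the start of chromosome 11, from 3023257 to 3103930, where 26 H3K4me3 peaks covered 67 kb, the largest such length among H3K4me3 runs joined within 5 kb. The run held 1 H3K27ac peak and 0 peaks of H3K4me1 and H3K27me3, and it was singled out after these values were seen. The control used for calling is not given, and whether the run reflects H3K4me3 enrichment was not tested.

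The H3K4me3 run with the second largest covered length, on chromosome 7 at 38960784 to 38986429, held 10 H3K4me3 peaks over 20.9 kb and 0 peaks of the other marks. On chromosome Y, the H3K27me3 peaks lay between 1788330 and 2895283, and the other 3 lists held 0 peaks.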
